A study of Homo sapiens with 12 samples.

How the data were processed

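RNA of primary human umbilical vein endothelial cells was measured on 12 one-colour 60-mer oligonucleotide arrays, 3 for each of 4 conditions held for 24 hours: low shear (1 dyne/cm2), high shear (15 dyne/cm2), reversing flow, whose shear stress the labels do not state, and static culture. Per the labels, confluent cells of passage 3 to 5 on glass slides were exposed in a parallel plate chamber, and total RNA was extracted with TRI-zol, treated with DNase, cleaned on columns and amplified linearly with Cy3-labelled CTP. The labels describe 3 independent experiments with different lots of cells. Each slide held 4 arrays, those of 1 replicate number, so slide, experiment and lot coincide. Each condition held the same position on every slide, so an effect of position cannot be told apart from that of condition. Time course and protein levels were not analysed here, because the series holds no such data.

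The deposited scanner files hold intensity values. Per the file headers, they were extracted with Agilent Feature Extraction 9.5.1.1, with local background subtraction, spatial and multiplicative detrending, and surrogate values for dim spots. The deposited series matrix holds log2 values, a unit read from their fit to the scanner files, with a median of 0 for each probe over the arrays and 1 offset per array. In the matrix the medians over probes were 0.0419, -0.183, 0.194 and -0.106 for low shear, high shear, reversing flow and static array 1, 0.143, 0.0994, 0.0121 and -0.0545 for the arrays of number 2, and 0.0751, -0.0531, -0.0555 and -0.0848 for those of number 3. Over 19626 probes the slope of the matrix against the scanner values was 1.00 once each probe was taken relative to low shear array 1, so scale, direction and the centring of probes are known from the values, while the scaling between arrays is not given in the sources used here. The main results were computed from the scanner files, and the matrix served as an alternative.

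Each array had 45015 features, with 41000 gene probes. The share of probes well above background was 50.3% and 52.5% on low shear array 2 and high shear array 2, where the local background was 593 and 440, and up to 71.8% elsewhere. At most 265 spots of an array were saturated. Control spots and the 874 spots marked as outliers over all arrays were left out and the spots of a probe averaged. Signals were taken as log2 and the array's 75th percentile was subtracted. Probes were kept if well above background on all 3 arrays of at least 1 condition, with at least 2 values per condition, and the brightest probe stood for its gene. Names came from the reference table by accession for 23593 probes, by symbol for 2794 and by synonym for 1119, and from the array file for 2194, while 11167 stayed unnamed and kept their probe number. A further 133 probes of Y-linked genes and XIST were left out. This gave 20287 genes, 20193 of them with a value on all 12 arrays. Of the called genes with several probes, 16 of 377, 15 of 358 and 13 of 375 had a probe of opposite sign for high shear, low shear and reversing flow against static culture.

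The 4 condition means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual and 2.77 prior degrees of freedom. The 6 pairwise comparisons and a moderated F test were adjusted with Benjamini-Hochberg, and genes were called at an adjusted p under 0.05. Differences are given as the first condition minus the second. Where a gene was not well above background on any array of a condition, the fold is a bound from the lowest signal well above background. Lists of genes, 28 with at least 5 measured members, were written before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison, which made 168 tests. Camera with an estimated correlation and limma's fry were the alternatives, and members were also adjusted over the list alone. Overlaps were set beside 100 simulations of unchanged groups. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

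The genes named were set by a rule fixed before the data were examined: 13 genes of endothelial biology, the 8 largest rises and 8 largest falls among called genes with the same sign on 3 slides and a signal well above background on all arrays, up to 3 genes with a bound in each direction, and up to 4 members of each list by smallest adjusted p.

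Whether arrays of 1 number belong together was checked from the deviations of each array from its condition's mean, which correlated between low and high shear by 0.839, 0.648 and 0.802 in experiments 1, 2 and 3. They correlated by 0.403, 0.288 and 0.186 between high shear and static culture, 0.347, 0.0837 and 0.108 between low shear and static culture, and -0.110, 0.115 and 0.0778 between reversing flow and static culture. For reversing flow they were -0.141, 0.204 and -0.204 with high shear and -0.00056, 0.186 and -0.00407 with low shear. The pairing itself comes from the labels, which describe independent experiments with separate lots, and among arrays of other conditions, 10 of the 12 correlated best with an array of their own number. Fits with the experiment as a fixed block were therefore run beside the others, and as a random block with a correlation of 0.171.

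The fits were tested on simulated data, in which 8% of genes changed 2-fold and 40% of genes changed 4-fold were called with 3 arrays per condition. In the same simulated set 2 unchanged genes and 0 genes in the wrong direction were called. A count of 0 called genes thus leaves room for many changes of 2-fold. In another simulated set the shifted list was called, and 0 of 27 unshifted lists were. Simulated genes varied independently, while in the data the estimated correlation was 0.92 for metallothioneins and 0.55 for mitosis genes. The simulation therefore cannot judge list calls at the preset correlation. The alternatives were normexp background correction with an offset of 50, quantile and median scaling, the series matrix, no filter on dim probes, only probes well above background on all 12 arrays, marked spots kept, the mean of a gene's probes, every probe on its own, a trend with robust variance, only the 6 arrays compared, and each array and experiment left out in turn. Between 75th percentile and median scaling the median log2 fold change over all genes moved from -0.08 to 0.08 for high shear, from -0.04 to 0.13 for low shear and from 0.06 to 0.21 for reversing flow, each against static culture.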

Results

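Human umbilical vein endothelial cells (HUVEC), primary cells that line the vein of the umbilical cord, were grown to a confluent layer and kept for 24 hours in 1 of 4 conditions. These were steady laminar flow at a high shear stress of 15 dyne/cm2, steady flow at a low shear stress of 1 dyne/cm2, reversing flow, and static culture without flow. Flow of low shear stress or changing direction is the kind found where atherosclerotic lesions form, and the title of the series names such flow as its subject. Each condition was measured in 3 independent experiments, each with another lot of cells, which gave 12 single-colour 60-mer oligonucleotide arrays with 41000 gene probes each. The 4 arrays of an experiment lay on the same slide, and each condition held the same position on every slide. The share of probes well above background ran from 50.3% on low shear array 2 and 52.5% on high shear array 2 to 71.8% on static array 1, and the 75th percentile of the processed signal ran from 1324 to 4157. Log2 fold changes below are given with the standard error of the limma fit, with n = 3 arrays per condition, and the number of arrays limits their precision. The p-values of the main fit measure the spread between the 3 arrays of a condition, pooled over the 4 conditions and without regard to the pairing by experiment.

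High shear was set against static culture to ask what steady flow at 15 dyne/cm2 changed. The transcription factors KLF4 and KLF2, which flow is known to induce in endothelium, rose by 4.32 ± 0.31 (19.9-fold, adjusted p = 9.95e-05) and 1.92 ± 0.33 (3.79-fold, adjusted p = 0.00592) on the log2 scale. CYP1B1, a cytochrome P450 induced by the aryl hydrocarbon receptor, rose 131-fold (7.03 ± 0.88, adjusted p = 0.00123), or by 6.38 without static array 2 and 7.89 without static array 3. The potassium channel KCNK3 rose 78.3-fold, the matrix proteoglycan gene VCAN 37.4-fold and PMEPA1, a known target of TGF-beta signalling, 20.9-fold. FCN3, which encodes the lectin ficolin-3, rose 20.4-fold, from -4.80 ± 0.16 to -0.46 ± 0.66 (log2 relative to the 75th percentile, SD, n = 3). Among the genes that fell, DEPP1 changed by -5.01 ± 0.62 (-4.35 without high shear array 3), PALD1 by -4.98 ± 0.52, the tight junction gene CLDN5 by -3.49 ± 0.39 and APLN, the ligand of the apelin receptor, by -3.56 ± 0.63. Several genes lay below background in all 3 arrays of 1 condition and have only a bound. MYOM3 was at least 28.1-fold higher, NPPC, which encodes C-type natriuretic peptide, at least 25.1-fold higher and the bradykinin receptor gene BDKRB2 at least 18.9-fold higher under high shear. The receptor kinase gene KIT was at least 41.7-fold lower and the retinoic acid hydroxylase gene CYP26B1 at least 34.7-fold lower. Both limits were more than 1.5 times as high without the high-background high shear array 2 (60.9-fold for CYP26B1). In the files' hg18 coordinates, the KLF4 probe lies on chromosome 9 at 109287870 to 109287929, that of KLF2 on chromosome 19 at 16299246 to 16299305 and that of CYP1B1 on chromosome 2 at 38148948 to 38149007.

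**Figure D1:**
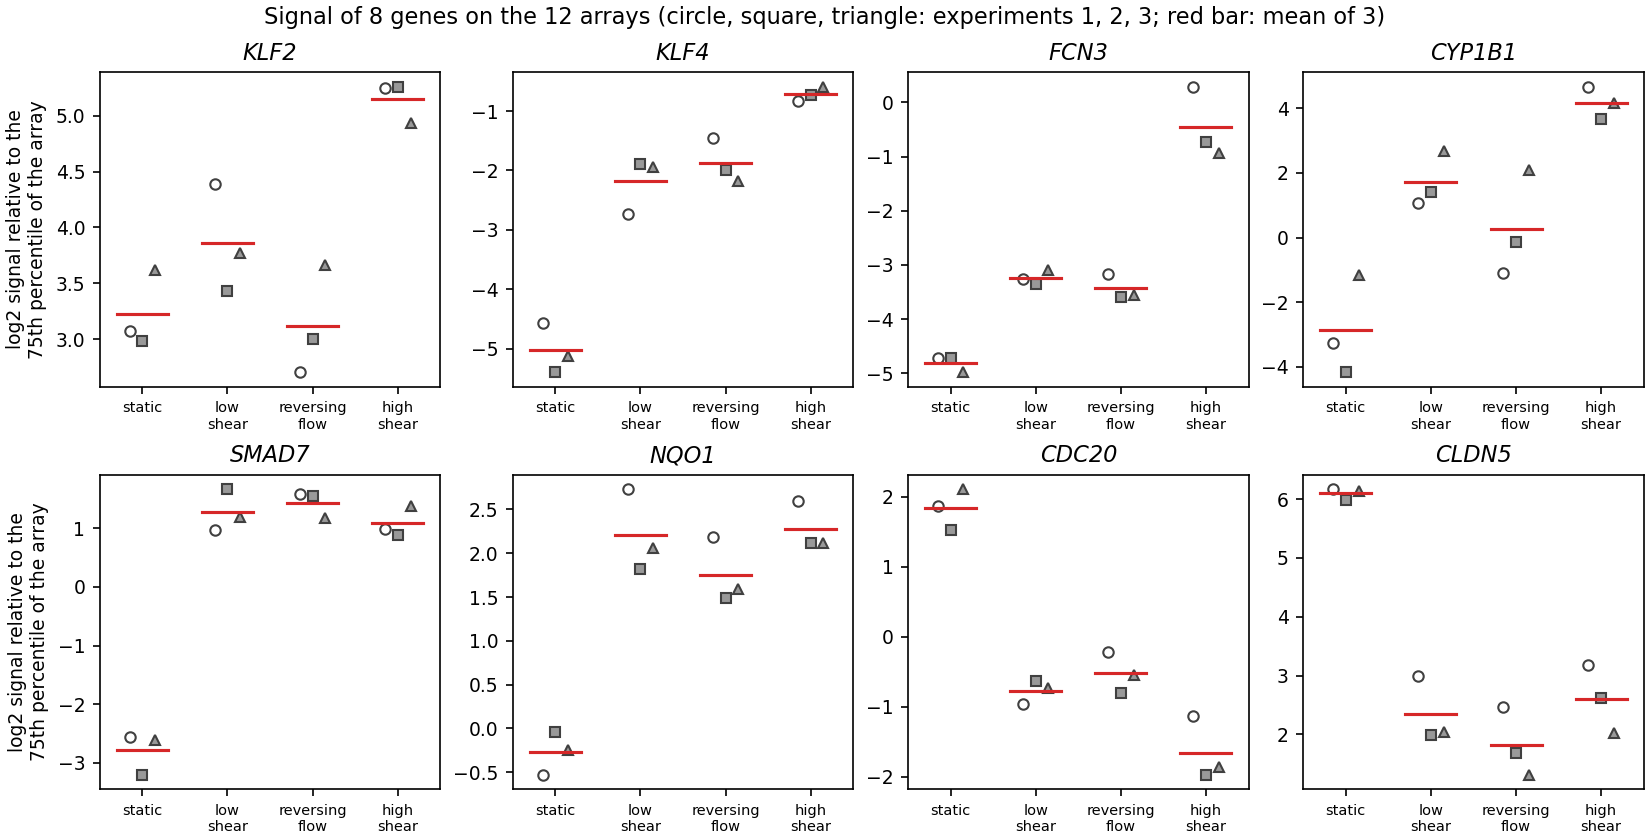
Log2 signal relative to the array's 75th percentile (y axis) for KLF2, KLF4, FCN3, CYP1B1, SMAD7, NQO1, CDC20 and CLDN5 in the 4 conditions (x axis), with circles, squares and triangles for experiments 1, 2 and 3 and a red bar at the mean of the 3 arrays. KLF4 has means of -0.72 under high shear and -5.03 in static culture, and CDC20 has means of -1.65 and 1.83.

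The gene lists fixed in advance showed the same comparison by function. Of the 30 mitosis genes measured, 28 fell and none rose (median -2.72), among them the anaphase activator CDC20 by 3.48 ± 0.28, the spindle checkpoint kinase BUB1B and the spindle motor KIF11, and all 30 fell when adjusted over the list alone. With limma's camera test the list had an adjusted p of 7.5e-33, and 0.0536 with an estimated correlation. Of 30 DNA replication genes, 23 fell (29 when adjusted over the list alone, median -1.82), including MCM2, a subunit of the replicative helicase, by 2.68 ± 0.20, and this list kept its call (adjusted p = 0.0298 with an estimated correlation). Of 17 genes of BMP and SMAD signalling, 9 rose (11 when adjusted over the list alone, median 1.57), with the inhibitory SMAD7 up 14.6-fold, SMAD6 by 3.46 ± 0.56 on the log2 scale and ID1 4.62-fold (adjusted p = 5.8e-10, and 0.0277 with an estimated correlation). Of 10 genes associated with KLF2 and KLF4, 5 rose (also 5 when adjusted over the list alone, median 1.54), including PLVAP, which forms the diaphragms of endothelial fenestrae, and the prostaglandin D synthase PTGDS. That list and the 7 aryl hydrocarbon receptor targets, of which 3 rose (5 when adjusted over the list alone, median 1.38), kept their calls, each with an adjusted p of 0.0277 with an estimated correlation. These 4 calls at an estimated correlation were lost with the experiment as a block (0.0580 for DNA replication and aryl hydrocarbon receptor targets, 0.0741 for BMP and SMAD genes, 0.0974 for the KLF2 and KLF4 list) and without the 2 high-background arrays (0.0970 each). Without reversing flow array 1, those of DNA replication (0.0991) and of the KLF2 and KLF4 list (0.0592) were lost. The nitric oxide synthase NOS3, a member of the KLF2 and KLF4 list, stood at 0.61 ± 0.39 (adjusted p = 0.474) and thrombomodulin, THBD, at 0.58 ± 0.38 (adjusted p = 0.476). CYP1A1, another cytochrome P450 induced by the aryl hydrocarbon receptor, was not called by limma under any flow condition. Against static culture it had 1.098, 0.351 and 0.101 under high shear, low shear and reversing flow (limma adjusted p = 0.331, 0.777 and 0.94). In the same order, it was called in 0 of 24, 0 of 24 and 0 of 23 settings.

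Of 23 NRF2 targets, genes of the antioxidant response, 4 rose (9 when adjusted over the list alone, median 0.88) and all 23 had positive values. NQO1 rose 5.85-fold and the cystine transporter SLC7A11 4.66-fold (list adjusted p = 7.6e-11, and 0.187 with an estimated correlation). Haem oxygenase, HMOX1, had 1.53 ± 0.41 (adjusted p = 0.0514, and 0.0492 with the experiment as a block). Of 24 genes of cholesterol synthesis, 3 rose and 1 fell (10 and 2 when adjusted over the list alone, median 0.50), with an adjusted p of 0.0011 and 0.0983 with an estimated correlation. Of 13 genes tied to endothelial to mesenchymal transition, 2 rose (4 when adjusted over the list alone, median 1.14), the repressors ZEB2 by 1.47 ± 0.20 and SNAI1 by 2.77 ± 0.70 (adjusted p = 0.0537 for SNAI1 with the experiment as a block, and from 0.0893 to 0.137 without any single array of the 6). That list had an adjusted p of 0.0085, and 0.0983 with an estimated correlation. Of 17 Notch and arterial genes, 5 rose (6 when adjusted over the list alone, median 0.99), and the list's adjusted p of 0.026 became 0.601 with an estimated correlation, 0.0508 without reversing flow array 1 and 0.0566 with median scaling.

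Over all genes, limma with Benjamini-Hochberg adjustment called 1317 of 20287 between high shear and static culture, 539 higher and 778 lower, and each had the same sign in all 3 experiments. Scaling to the median in place of the 75th percentile gave 725 higher and 601 lower. The count was 836, 861 and 699 without high shear array 1, 2 or 3 and 596, 663 and 649 without static array 1, 2 or 3. It was 2779, 111 and 34 without experiment 1, 2 or 3, and 2828 without reversing flow array 1, whose values enter the shared spread, and 785 without low shear array 2 and high shear array 2, the arrays of highest background. KLF4, KCNK3, PMEPA1, FCN3, MPP4 and SMAD7 passed in each of these fits. KLF2 was lost without experiment 2 (adjusted p = 0.213) or 3 (0.112), CYP1B1 and VCAN without experiment 2 (0.0778 and 0.0701), and NQO1 without experiment 2 (0.059) or 3 (0.105). Apart from MYOM3 and CYP26B1, the other called genes named above for this comparison were also lost without experiment 2 or 3.

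Low shear was set against static culture in the same way. KLF4 rose 7.21-fold (2.85 ± 0.31, adjusted p = 0.00088), while KLF2 had 0.64 ± 0.33 (adjusted p = 0.322). Large rises were those of KCNK3 (27.2-fold), CYP1B1 (23.8-fold), the cytokine IL11 (22.1-fold), ID2, an inhibitor of helix-loop-helix transcription factors (20.4-fold), and the aldo-keto reductase AKR1C1 (18.7-fold), each in 3 of 3 experiments. The naming rule required the same sign in 3 experiments of the largest rises. The call of CYP1B1 (adjusted p = 0.0133) was lost without static array 1 (0.066), static array 2 (0.0616), low shear array 3 (0.0529), both high-background arrays (0.0507) or experiment 2 (0.248). Its log2 change was 3.92 without static array 2 and 5.43 without static array 3. CD34, a surface glycoprotein of endothelial and blood progenitor cells, fell by 5.00 ± 0.65, DEPP1 by 5.40 ± 0.62, APLN by 4.36 ± 0.63 and CLDN5 by 3.75 ± 0.39. CLEC1B was at least 49.8-fold higher and GPR83 at least 14.9-fold higher than in static culture, where neither was well above background on any array, and KIT was at least 32.6-fold lower (55.0-fold without the high-background low shear array 2).

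By list, 9 of 23 NRF2 targets rose (19 when adjusted over the list alone, median 1.32), with NQO1 up 5.58-fold and HMOX1 at least 4.34-fold, since its probe was saturated on 1 low shear array (adjusted p = 0.0134 for HMOX1, 0.0724 without static array 1, 0.063 without static array 3, 0.0697 without the high-background arrays, and 0.172 and 0.233 without experiment 2 or 3). The list had an adjusted p of 5.7e-14, and 0.15 with an estimated correlation. Of 17 BMP and SMAD genes, 10 rose (11 when adjusted over the list alone, median 1.33), among them SMAD7 (16.7-fold, adjusted p = 0.000142) and the pseudoreceptor BAMBI (4.89-fold), and the list kept its call (adjusted p = 0.0491 with an estimated correlation). Of 7 aryl hydrocarbon receptor targets, 3 rose (4 when adjusted over the list alone, median 0.76), also with 0.0491 with an estimated correlation. At an estimated correlation both calls were lost with the block (0.0911 for the receptor targets and 0.0913 for BMP and SMAD genes), with median scaling (0.0775 each), without the 2 high-background arrays (0.159 each) and without reversing flow array 1 (0.0750 and 0.0717). Mitosis genes fell in 23 of 30 cases (28 when adjusted over the list alone, median -2.19, adjusted p = 0.113 with an estimated correlation), and DNA replication genes in 22 of 30 (26 when adjusted over the list alone, median -1.52, adjusted p = 0.0629 with an estimated correlation). KIF11 fell by 2.48 ± 0.25 and MCM2 by 2.20 ± 0.20. Of the 10 genes associated with KLF2 and KLF4, 2 rose and 1 fell (2 and 2 when adjusted over the list alone), and the list was not called (adjusted p = 0.21).

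The remaining called lists each lost their call with an estimated correlation. The 10 metallothioneins, which bind heavy metals, had a median of 1.23, and of 1.88, 2.11 and -0.28 in the 3 experiments, with none called singly (0 when adjusted over the list alone, adjusted p = 0.525 with an estimated correlation). Of 16 p53 targets, 4 rose (4 when adjusted over the list alone, median 0.23), including the cell cycle inhibitor CDKN1A by 1.75 ± 0.36, whose call was lost without static array 1 (adjusted p = 0.0915), static array 3 (0.0591), low shear array 1 (0.0522), experiment 2 (0.152) or experiment 3 (0.253). The list's adjusted p was 0.042, 0.469 with an estimated correlation and 0.0654 with the experiment as a block. Of 6 lymphatic endothelial genes, 2 fell (3 when adjusted over the list alone, median -1.23), with 0.047, 0.15 with an estimated correlation, 0.0842 with the block and 0.0816 without reversing flow array 1. For 13 genes of endothelial to mesenchymal transition, 2 rose (4 higher and 1 lower when adjusted over the list alone), with 0.012 and 0.138 with an estimated correlation.

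In all, limma called 1201 genes between low shear and static culture, 480 higher and 721 lower, each with the same sign in 3 experiments, and 646 higher and 537 lower with median scaling. The count was 795 and 666 without low shear array 1 or 3, and 375, 502 and 507 without static array 1, 2 or 3. It was 2785, 52 and 29 without experiment 1, 2 or 3, and 3303 without reversing flow array 1. Without low shear array 2 and high shear array 2, the arrays of highest background, 712 genes were called. SMAD7, CLEC1B and GPR83 passed in each of these fits. KLF4 was lost without experiment 2 (adjusted p = 0.108) or 3 (0.0938), as was each other called gene named above for this comparison without at least 1 of these experiments.

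Reversing flow was set against static culture to ask what flow of changing direction changed. DEPP1 fell by 6.11 ± 0.62 (69.0-fold, adjusted p = 0.000618), PALD1 by 5.69 ± 0.52, the retinal reductase DHRS3 by 5.68 ± 0.53, CD34 by 5.49 ± 0.65 and CLDN5 by 4.28 ± 0.39 on the log2 scale, each in 3 of 3 experiments. For the largest falls the naming rule required the same sign in 3 experiments. KLF4 rose 8.91-fold (3.15 ± 0.31, adjusted p = 0.000594), and KLF2 had -0.11 ± 0.33 (adjusted p = 0.887). ID2 rose 32.9-fold, IL11 27.0-fold, AKR1C1 19.8-fold and SMAD7 18.7-fold (adjusted p = 7.03e-05). Reversing flow array 1 raised part of these: without it the log2 changes were 3.83 for ID2, 4.01 for IL11, 3.56 for AKR1C1 and -4.59 for CD34, and without array 3 they were 5.71 for ID2 and -6.10 for CD34. CYP1B1 had 3.14 ± 0.88 (adjusted p = 0.0621, and 0.0188 with the experiment as a block), 3.83 without reversing flow array 1 (0.0382), 2.24 without array 3, and 2.48 and 3.99 without static array 2 or 3 (0.213 and 0.0411). CLEC1B was at least 40.1-fold higher (24.8-fold without reversing flow array 1 and 61.2-fold without array 2) and the myosin gene MYO5C at least 50.5-fold lower. SMAD7 is read by a probe on chromosome 18 at 44700780 to 44700839 (hg18), DEPP1 by 1 on chromosome 10 at 44791716 to 44791775.

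Of 23 NRF2 targets, 9 rose (19 when adjusted over the list alone, median 1.36, adjusted p = 0.185 with an estimated correlation), with NQO1 up 4.07-fold. Of 17 BMP and SMAD genes, 8 rose (10 when adjusted over the list alone, median 1.05), and of 7 aryl hydrocarbon receptor targets 3 (4 when adjusted over the list alone, median 1.18), both with an adjusted p of 0.0954 with an estimated correlation. Mitosis genes fell in 19 of 30 cases (27 when adjusted over the list alone, median -1.66) and DNA replication genes in 17 of 30 (27 when adjusted over the list alone, median -1.50), with 0.167 and 0.0954 with an estimated correlation. CDC20 fell by 2.35 ± 0.28 and MCM2 by 2.23 ± 0.20. For endothelial to mesenchymal transition, 3 of 13 genes rose (4 higher and 1 lower when adjusted over the list alone), with a list adjusted p of 0.004 and 0.11 with an estimated correlation, and ZEB2 rose by 1.66 ± 0.20. The 10 metallothioneins had a median of 1.89 with none called over all genes (10 higher when adjusted over the list alone, adjusted p = 0.335 with an estimated correlation), and medians of 3.46, 1.93 and 0.21 in the 3 experiments. Their estimated correlation was 0.92, so the 10 members are not 10 separate results in any comparison. Whether their probes tell these genes apart was not tested.

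A further 7 lists were called in this comparison and lost the call without reversing flow array 1, which stood apart from the other two arrays of its condition. The 23 pan-endothelial genes had a median of -0.72, with 5 lower (2 higher and 6 lower when adjusted over the list alone), among them CD34 and CLDN5. Their adjusted p was 0.00069, 0.37 with an estimated correlation and 0.134 without that array. In the same order, the values were 0.014, 0.442 and 0.219 for angiogenesis genes, 0.042, 0.544 and 0.61 for the heat shock response, 0.045, 0.442 and 0.346 for coagulation genes, 0.045, 0.185 and 0.134 for epithelial markers, 0.045, 0.335 and 0.256 for hypoxia genes, and 0.049, 0.544 and 0.383 for immediate early genes. After the angiogenesis list, their medians were 0.88, -0.76, -0.87, 0.36 and 1.30, and the immediate early list had 0.0724 with the experiment as a block, 0.112 with median scaling and 0.0553 without the 2 high-background arrays. The heat shock list had 0.0563 with median scaling and the epithelial list 0.053 without the high-background arrays. Of their members, 2 angiogenesis, 2 coagulation and 1 epithelial gene fell and 1 hypoxia gene rose. Adjusted over the list alone, 5, 5 and 3 fell in the first 3 of these, 2 hypoxia genes were higher and 1 lower, and 2 immediate early genes were higher. The heat shock genes had medians of 2.71, 0.25 and 0.04 in experiments 1, 2 and 3, and the immediate early genes 2.80, 0.05 and -0.28.

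**Figure D2:**
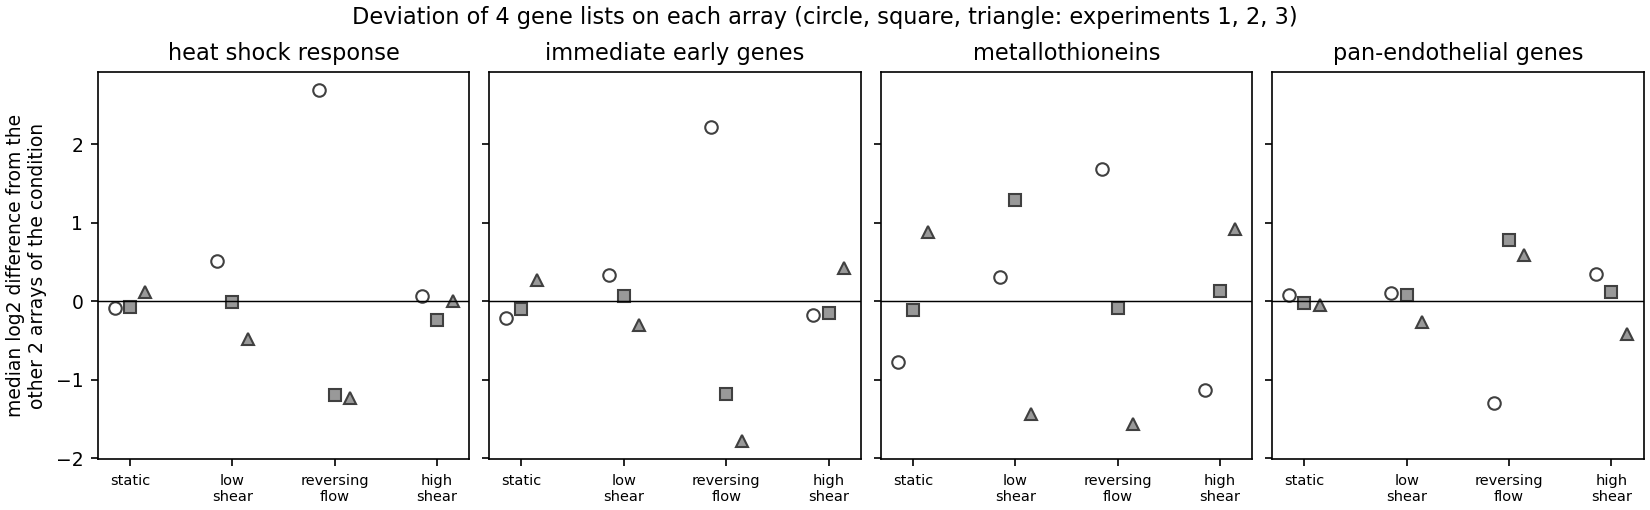
Median log2 difference (y axis) of each array from the mean of the other two arrays of its condition, for heat shock, immediate early, metallothionein and pan-endothelial genes, over the 12 arrays (x axis). Reversing flow array 1 lies at 2.69 for heat shock genes, 2.22 for immediate early genes and -1.30 for pan-endothelial genes, while the other 11 arrays lie between -1.23 and 0.52 for heat shock genes.

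Across all genes limma called 1254 between reversing flow and static culture, 494 higher and 760 lower with the same sign in 3 experiments each, and 595 higher and 617 lower with median scaling. That count was 335, 496 and 501 without static array 1, 2 or 3, and 1926, 40 and 120 without experiment 1, 2 or 3. It was 1494 without reversing flow array 1. SMAD7, PALD1, DHRS3, CLEC1B and MYO5C passed in each of these fits. KLF4 was lost without experiment 2 (adjusted p = 0.077), as were the other called genes named above for this comparison.

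The 3 flow conditions were compared with static culture on the same static arrays, so the overlaps carry a shared part. High and low shear shared 361 higher and 543 lower genes, high shear and reversing flow 324 and 478, and low shear and reversing flow 378 and 532, with 0 genes called in opposite directions in limma's fits. Genes called in all 3 comparisons numbered 300 higher, including KLF4, SMAD7, NQO1, PTGS2 and MMP10, and 432 lower, including CLDN5, CDC20, MCM2 and CD34, out of 1888 called in at least 1. Independent lists of these sizes would share 12.8 higher and 27.7 lower genes for high and low shear. Simulated unchanged groups shared at most 1 gene in 100 simulations. Unchanged groups give few calls in any case, so that count cannot show how much of the overlap comes from the shared static arrays. The log2 fold changes correlated across genes with r = 0.886, 0.733 and 0.863 for the 3 pairs in the order above, against 0.501, 0.501 and 0.502 in simulated unchanged groups, and genes are not independent replicates. The covariances were 0.628, 0.559 and 0.669 beside a simulated 0.134, 0.134 and 0.135, differences of 0.494, 0.425 and 0.535. With 3 static arrays the controls cannot be split. The simulated groups shared the static arrays, so the simulated correlations and covariances already hold that part. The simulation took arrays as independent, while arrays of 1 experiment deviated together, so part of the excess over it may come from the shared experiments.

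Low and high shear were compared to ask what the magnitude of steady flow alone changed. FCN3 fell by 2.78 ± 0.31 on the log2 scale from high to low shear (6.86-fold, adjusted p = 0.0456), by 3.55, 2.62 and 2.16 in experiments 1, 2 and 3, and it was the only gene called of 20287 by limma, with 404 at an unadjusted p under 0.05. Its probe lies on chromosome 1 at 27568413 to 27568472 in hg18 coordinates. The 10 measured genes associated with KLF2 and KLF4 were all lower under low shear, with a median of -1.38 and medians of -1.55, -1.38 and -1.19 in the 3 experiments. KLF2 had -1.29 ± 0.33, KLF4 -1.47 ± 0.31, THBD, which activates protein C on the endothelial surface, -1.49 ± 0.38 and PTGDS -1.72 ± 0.30, none of them called over all genes. Adjusted over the list alone, 0 were higher and 7 lower, and the list's adjusted p of 1.3e-22 by camera was 0.00117 with an estimated correlation. There it was 0.0205 with the experiment as a block, 0.00978 without the 2 high-background arrays, 0.00971 without reversing flow array 1 and 0.000495 with median scaling. Leaving out an experiment was not run at an estimated correlation.

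A further 12 lists were called between low and high shear with camera's preset correlation, and each lost its call with an estimated correlation. The 10 metallothioneins had a median of 1.96, and of 2.87, 2.65 and 0.39 in the 3 experiments (10 higher when adjusted over the list alone, adjusted p = 0.0768 with an estimated correlation). Mitosis genes had a median of 0.52, with CDC20 at 0.88 ± 0.28, DNA replication genes 0.27, NRF2 targets 0.27 and p53 targets 0.21, with 0.38, 0.425, 0.628 and 0.363 with an estimated correlation. Lower medians were found for cholesterol synthesis (-0.25, with 0.0633 with an estimated correlation), vasoactive mediators (-0.29, with 0.0633), pan-endothelial genes (-0.26, with 0.38), Notch and arterial genes (-0.41, with 0.425), coagulation (-0.32, with 0.363), extracellular matrix (-0.16, with 0.628) and aryl hydrocarbon receptor targets (-0.07, with 0.241). Adjusted over the list alone, 1 vasoactive gene was higher and 3 lower, 1 coagulation gene was lower, 1 p53 target was higher, and no member of the other lists passed. The aryl hydrocarbon receptor list also lost its call without reversing flow array 1 (0.0898) and without the 2 high-background arrays (0.157), and the NRF2 list without the latter (0.0749).

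The FCN3 call between low and high shear was lost without low shear array 1, 2 or 3 (adjusted p = 0.324, 0.436 and 0.174), without high shear array 2 or 3 (0.191 and 0.0624) and without experiment 1, 2 or 3 (0.151, 1 and 1). It was also lost without the 2 high-background arrays (adjusted p = 1) and with only the 6 arrays compared (1). Other processing ended it too: normexp background (0.0705), quantile scaling (0.0743), the series matrix (0.051), no dim filter (0.166), every probe on its own (0.0574) and a robust trend (0.0559), so FCN3 was called in 8 of 24 settings. With the experiment as a block 2 genes were called, FCN3 and VCAN (-3.48, adjusted p = 0.0358), the latter named after its value was seen. Without reversing flow array 1 the count was 5.

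Reversing flow was compared with high shear, the contrast closest to the title of the series. FCN3 fell by 2.98 ± 0.31 on the log2 scale (7.88-fold, adjusted p = 0.0233), and by 3.45, 2.85 and 2.62 in experiments 1, 2 and 3. All 10 genes associated with KLF2 and KLF4 were lower, with a median of -1.32, and of -2.05, -1.24 and -0.97 in the 3 experiments. KLF2 had -2.03 ± 0.33 (4.09-fold, adjusted p = 0.485), KLF4 -1.16 ± 0.31, THBD -1.95 ± 0.38 and NOS3 -1.21 ± 0.39. Adjusted over the list alone, 7 were lower, and the list's adjusted p of 4e-11 was 0.0151 with an estimated correlation, a call lost there with the experiment as a block (0.113) and without the 2 high-background arrays (0.0796). CYP1B1 had -3.89 ± 0.88 (adjusted p = 0.583; -3.20 without reversing flow array 1 and -4.79 without array 3), the receptor for natriuretic peptides NPR1 -2.19 ± 0.43 (adjusted p = 0.583) and the leukocyte adhesion molecule ICAM1 -1.63 ± 0.50 (adjusted p = 0.583; -1.04 and -2.29 without the same arrays).

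Of the other 12 lists called here, none kept its call with an estimated correlation. Metallothioneins, whose members moved together, had a median of 2.60 (10 higher when adjusted over the list alone, adjusted p = 0.216 with an estimated correlation) and medians of 4.49, 2.44 and 0.98 in the 3 experiments. Mitosis genes had a median of 0.86 (12 higher when adjusted over the list alone, adjusted p = 0.367 with an estimated correlation), with the kinetochore motor CENPE at 1.53 ± 0.34. DNA replication genes had 0.38 and heat shock genes 0.63, with 0.505 and 0.662 with an estimated correlation. Pan-endothelial genes had -0.68, Notch and arterial genes -0.79, vasoactive mediators -0.52, cholesterol synthesis -0.29 and aryl hydrocarbon receptor targets -0.52, with 0.289, 0.393, 0.143, 0.225 and 0.216 with an estimated correlation. Angiogenesis genes had -0.79, coagulation genes -0.69 and extracellular matrix genes -0.45, with 0.393, 0.367 and 0.541. Without reversing flow array 1 the calls of the last 3 and of the heat shock genes were lost (0.119, 0.113, 0.677 and 0.246), and without the 2 high-background arrays those of cholesterol synthesis (0.0501), aryl hydrocarbon receptor targets (0.0649), extracellular matrix (0.0817) and heat shock genes (0.0817). Adjusted over the list alone, 2 aryl hydrocarbon receptor targets, 1 vasoactive and 1 coagulation gene were lower and no member of the remaining lists passed.

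**Figure D3:**
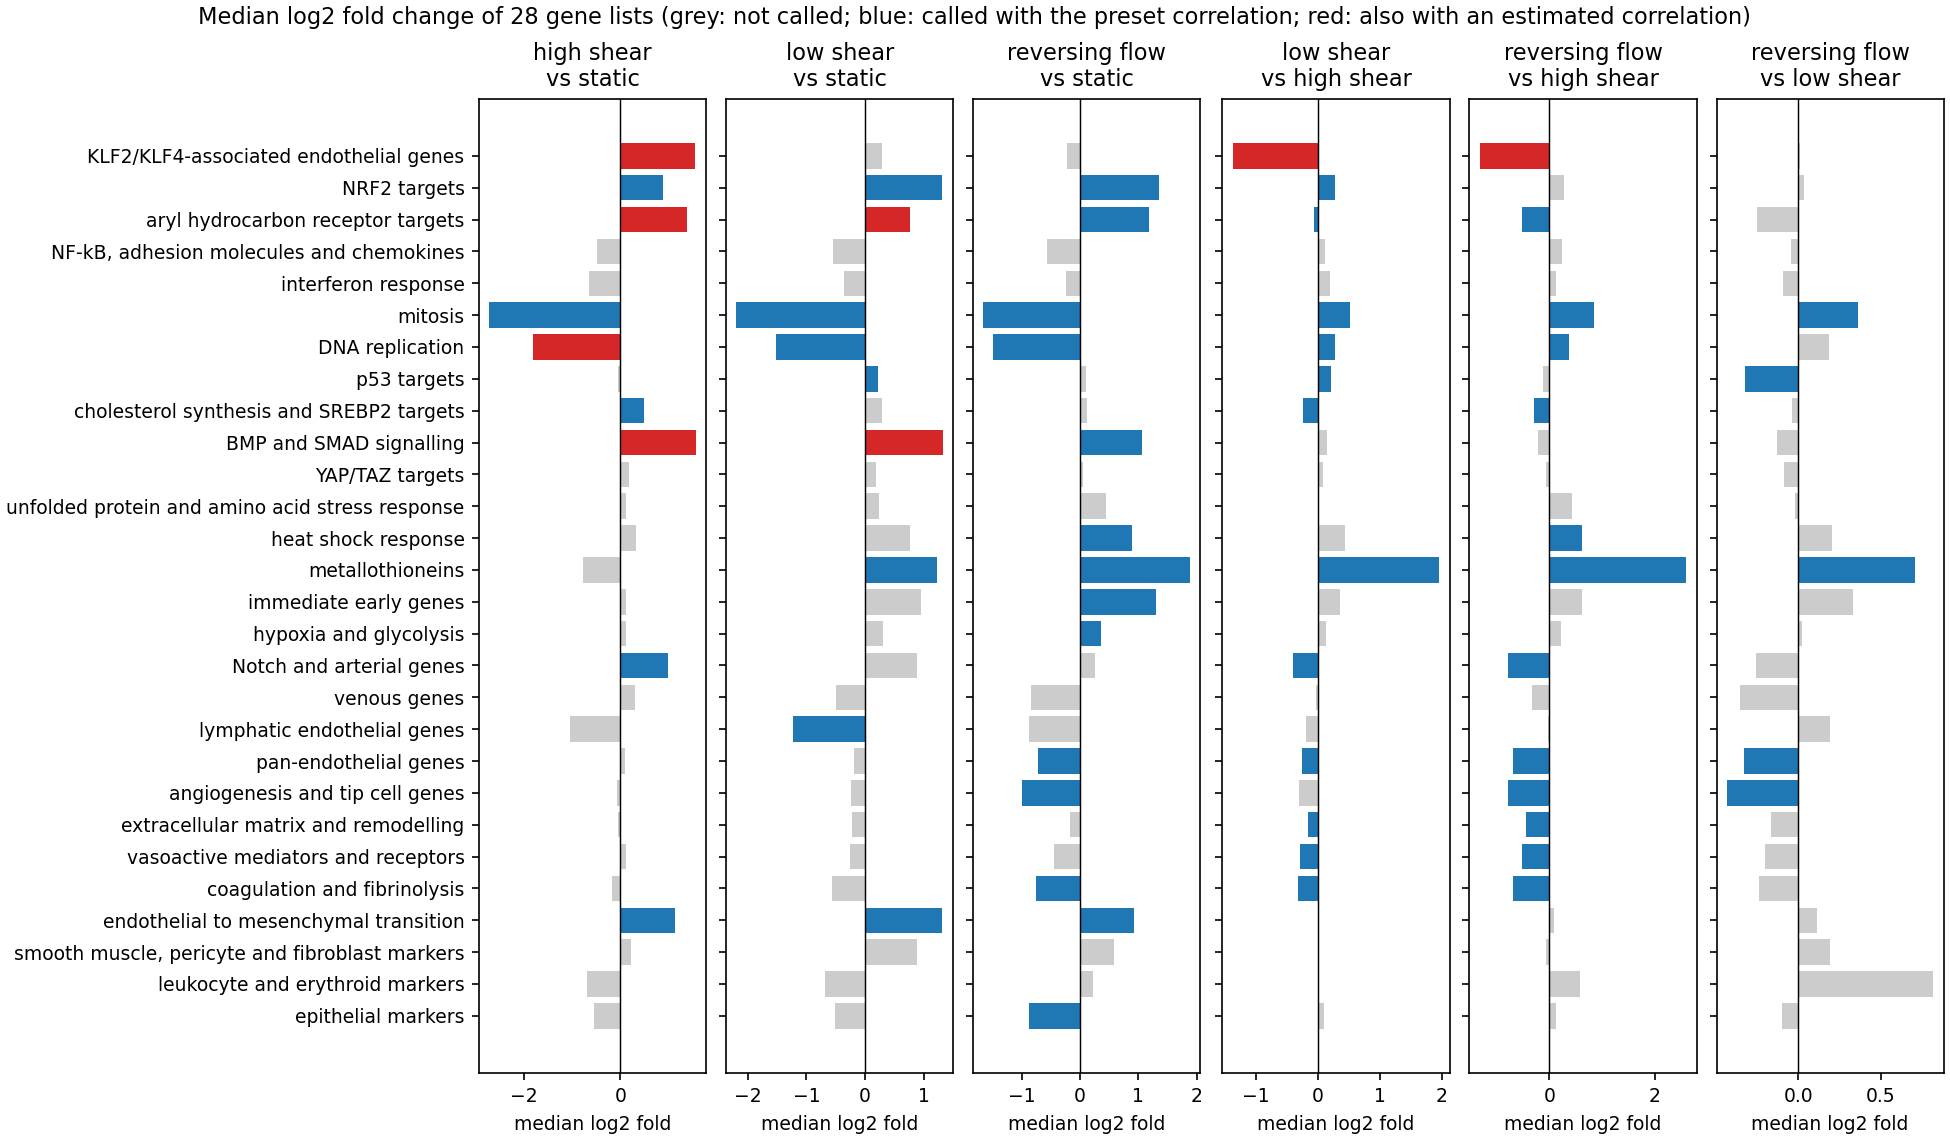
Median log2 fold change (x axis, with its own scale in each panel) of the 28 gene lists (y axis) in the 6 comparisons, with grey for lists not called, blue for lists called with the preset correlation only and red for those also called with an estimated correlation. The genes associated with KLF2 and KLF4 are red at -1.38 and -1.32 for low shear and reversing flow against high shear and at 1.54 for high shear against static culture.

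FCN3 was the only gene limma called between reversing flow and high shear, with 1258 at an unadjusted p under 0.05. Its call was lost without reversing flow array 2 or 3 (adjusted p = 0.235 and 0.115), high shear array 2 (0.107) or experiment 1, 2 or 3 (0.0681, 0.705 and 0.371), without the 2 high-background arrays (0.341) with only the 6 arrays compared (0.728) and with no dim filter (0.0865), so that it was called in 14 of 23 settings. With the experiment as a block, FCN3 and VCAN were called (VCAN -3.12, adjusted p = 0.0432), and without reversing flow array 1 the count was also 2. FCN3 was thus called in both comparisons with high shear, an overlap of 1 gene, or 2 with the block. The covariance of the 2 sets of log2 fold changes across genes was 0.180 beside 0.134 in simulated unchanged groups that share the high shear arrays, a difference of 0.0464. Part of this difference may come from the shared experiments, which the simulation left out.

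Reversing flow was set against low shear to compare a changing with a steady flow direction. KLF2 had -0.74 ± 0.33, KLF4 0.31 ± 0.31 and THBD -0.46 ± 0.38, all with an adjusted p of 0.948. The genes associated with KLF2 and KLF4 had a median of 0.01 and an adjusted p of 0.73. The 5 lists called were mitosis (median 0.36), p53 targets (-0.32), pan-endothelial genes (-0.33), angiogenesis genes (-0.43) and metallothioneins (0.70). Each had an adjusted p of 0.74 with an estimated correlation, and none held without reversing flow array 1 (0.195, 0.0693, 0.643, 0.524 and 0.634), with 0 members passing when adjusted over the list alone. Without that array 5 other lists were called, among them NRF2 targets (median -0.38, adjusted p = 4.5e-10, and 0.122 with an estimated correlation) and immediate early genes (median -0.58, adjusted p = 7e-06, and 0.18 with an estimated correlation). Limma called 0 genes, with 285 at an unadjusted p under 0.05 and a smallest adjusted p of 0.948.

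Over all 4 conditions at once, limma's moderated F test called 983 genes. The count was 177, 256 and 242 without static array 1, 2 or 3, 2238 without reversing flow array 1, and 1495, 28 and 1 without experiment 1, 2 or 3. Among inflammatory genes chosen in advance, the chemokine CCL2 had -0.46 ± 0.91, -1.12 ± 0.91 and -2.04 ± 0.91 against static culture under high shear, low shear and reversing flow (adjusted p = 0.834, 0.563 and 0.212). The last was -0.84 without reversing flow array 1 and -3.16 without array 3 (adjusted p = 0.0321). E-selectin, SELE, had 0.73 ± 0.66, 0.82 ± 0.66 and 0.11 ± 0.66, and 0.12, 0.21 and -0.50 without static array 2. ICAM1 had 1.08, -0.19 and -0.55 in the same order (limma adjusted p = 0.284, 0.873 and 0.567). The last ranged from -1.215 to 0.038 over the settings. Between low and high shear ICAM1 had -1.27 ± 0.50 and was called in 0 of 24 settings. The adhesion molecule VCAM1 was well above background on 2 of the 3 static arrays and on none under flow, and was not tested. The endothelin gene EDN1, also chosen in advance, had 1.02, 1.56 and 0.55 under high shear, low shear and reversing flow against static culture. It was not called in the main limma fit (adjusted p = 0.419, 0.173 and 0.645), but was in 3 of 24, 3 of 24 and 2 of 23 settings. Its log2 signal was 3.33 on reversing flow array 1, and 6.06 and 6.02 on arrays 2 and 3. Under low shear it was 6.55, 5.92 and 5.94. Over the settings, the change of EDN1 under reversing flow ranged from -0.02 to 1.46, so the lower value there rests on array 1.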

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

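The tests of a signal curve, of the cell lot or slide and of gene length for reversing flow array 1, and that of the counts without this array, were chosen after the result was seen, as were the arrays left out in the tests of the KLF2 and KLF4 list. The conditions had groups of 3 arrays, which are too small for a test of single values that stand apart.

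The effect of flow against static culture was compared between flow conditions by a test of the difference itself. It differed for 1 gene, and of the 13, 13 and 5 lists called in the 3 comparisons at the preset correlation, only 1 kept its call with an estimated correlation, in both comparisons with high shear, although for reversing flow not with the experiment as a block (adjusted p = 0.113). FCN3 had -2.78 between low and high shear and -2.98 between reversing flow and high shear on the log2 scale, and the genes associated with KLF2 and KLF4 had medians of -1.38 and -1.32.

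For that list, the median between reversing flow and high shear was -1.15 without reversing flow array 1, and between low and high shear -1.30 without the 2 high-background arrays. The bound for a cause in these arrays, a median above -0.3, was written before the list was refitted, and both values argue against it. The position on the slide stays open, since 0 positions held more than 1 condition, and cannot be told apart from flow. A response of the KLF2 and KLF4 program to high shear is a possible explanation that the design names and that was not tested further, and between reversing flow and low shear the list had a median of 0.01 (adjusted p = 0.73).

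Reversing flow array 1 stood apart from the other two arrays of its condition, with heat shock genes at 2.69 and pan-endothelial genes at -1.30. A curve on mean signal took 3.54% of the variance of its deviations, and their highest correlation with those of the other arrays of experiment 1 was -0.00056, which argue against an array effect tied to signal and against the lot or slide. The labels were checked on 904 genes called in the same direction under high and low shear against static culture. On each of the 3 reversing flow arrays at least 99.0% of them moved as in the other flow conditions. This argues against a static culture array under a reversing flow label, but cannot tell 1 flow condition from another. A test of gene length was void, because only 66.2% of genes had a length in the reference table, a limit applied after the test's result was seen. An acute stress in this culture, or lower RNA or labelling quality, since this was the dimmest of the 12 arrays (75th percentile of 1324, next lowest 1757), is a possible explanation that was not excluded, and no biological condition in the labels sets this array apart.

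Few genes were called between flow conditions. Without reversing flow array 1 the highest of the 3 counts was 5, for low against high shear, which kept all its arrays. This argues against the spread of this array as the main cause there. That spread did limit calls, since high and low shear against static culture rose to 2828 and 3303. The comparisons with reversing flow kept fewer arrays of that condition, so their counts cannot decide. From the p-values of reversing flow against high shear, 23.1% of genes were estimated as changed, which met a bound of more than 5% set in advance for true differences too small for 3 arrays, but the estimate was 1.83% without that array, a condition added afterwards. With all arrays the estimate was 1.3e-05% for low against high shear and 2.65% for reversing flow against low shear (0.00087% and 8.69% with the experiment as a block). Whether many small differences exist cannot be told apart from the effect of reversing flow array 1 on the estimate.

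For each comparison the 10 splits of 6 arrays are too few for a share under 0.05. With low and high shear, the real split gave 1 gene and the highest other 43, and 5 splits gave at least as many as the real one. The split with 43 put low shear array 1, high shear array 1 and low shear array 2 together, which points to a structure of the samples other than condition. The other 3 splits with both arrays of experiment 1 together gave 0, 1 and 1, and the splits that parted all 3 pairs, as the real one does, gave 0. With reversing flow and high shear the real split gave 1 and the highest other 0 (1 split as large), and with reversing flow and low shear 0 and 1 (10 splits as large). Against static culture, high shear gave 1317, low shear 1201 and reversing flow 1254, with 0 in every other split (1 split as large in each). For the F test, 2 of 100 drawn splits reached 983 genes, the real one included, and the other gave 1221 and kept the 3 static arrays together. These splits were drawn without regard to the experiments. Only 4 of them put the 4 arrays of every slide in different groups, as the real one does, with 0 genes at most, and these are too few for a share under 0.05.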

How the results depend on the processing

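The fits without reversing flow array 1 and without the 2 high-background arrays were chosen after the data were seen, and the cause of changes below was not tested unless fewer genes or arrays were used by construction. Against static culture, the counts for high shear, low shear and reversing flow were 820, 696 and 624 without a filter on dim probes, where more genes were tested, and 513 for the F test. With the experiment as a fixed block, the pairing the labels describe, high shear gave 1825, low shear 1788, reversing flow 1788 and the F test 1313. With a random replicate block, reversing flow gave 2047 and the F test 1491. With only the 6 arrays compared, high shear gave 2757 and low shear 2011. Without reversing flow array 1, high shear gave 2828, low shear 3303 and the F test 2238, and without the high-background arrays high shear gave 785, low shear 712 and the F test 611. Between low and high shear, the count was 2 with the replicate block, the random replicate block or median scaling, 5 without reversing flow array 1, and 0 with normexp, quantile normalization, the series matrix values, no dim filter, every probe on its own, the robust trend, only the 6 arrays or without the high-background arrays. Between reversing flow and high shear it was 2 with the replicate block or median scaling and 0 with no dim filter, only the 6 arrays or without the high-background arrays, and between reversing flow and low shear 0 throughout.

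Leaving out an array of the conditions compared, or an experiment, gave 0 to 1 genes for low against high shear, 0 to 2 for reversing flow against high shear, 34 to 2779, 29 to 2785 and 40 to 1926 for high shear, low shear and reversing flow against static culture, and 1 to 2238 for the F test. Where an experiment was left out, 2 arrays per condition remained. Of 63 called list tests, 8 were called with an estimated correlation and fry called 35 (27 in both). With an estimated correlation, 7 were called without reversing flow array 1 and 1 without the high-background arrays, a choice also made after the data were seen. Without reversing flow array 1, 44 of the 63 were kept at the preset correlation and 12 others called, none of them with an estimated correlation, such as heat shock genes for low shear against static culture (adjusted p = 0.0288), low against high shear (0.00585) and reversing flow against low shear (0.000214). The overlap of the comparisons with high shear was 2 with the replicate block. Of 233 calls of named genes, 225 were kept with the replicate block and 26 gained, 219 with normexp, 215 with quantile scaling, 221 with median scaling, 159 without a dim filter and 160 without the high-background arrays. With the replicate block, SNAI1 was no longer called for low shear against static culture (adjusted p = 0.0503). Beyond this and the values beside the results, it changed no other call of a gene or list named in the report. Only NR2F2 changed sign past the threshold, with -0.23 for reversing flow against static culture, 0.78 without replicate 1 (adjusted p = 0.0462) and -0.76 without replicate 2. Signal over background limited low shear array 2 and high shear array 2 most, with 50.3% and 52.5% of probes well above it.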

Other observations

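The fits without the 2 high-background arrays, and the estimated correlations under other settings, were chosen after the data were seen. Prostaglandin synthase 2, PTGS2, rose under each flow condition against static culture, by 4.09 ± 0.35, 3.61 ± 0.35 and 3.51 ± 0.35 on the log2 scale for high shear, low shear and reversing flow. The protease MMP10 rose by 3.35, 3.38 and 3.21 and the hypoxia gene NDRG1 by 2.71, 2.44 and 2.21. The neutrophil chemokine CXCL1 fell by 2.97 ± 0.47 under high shear and 2.91 ± 0.47 under low shear, and by 2.26 ± 0.47 under reversing flow, where the call (adjusted p = 0.0196) was lost without reversing flow array 2 (0.0541), any static array (0.0706, 0.0814 and 0.0717) or experiment 2 or 3 (0.325 and 0.175). The NF-kB, interferon and YAP lists were not called against static culture by camera, which tests for a shared direction. For 26 NF-kB, adhesion and chemokine genes the adjusted p was 0.165, 0.212 and 0.14 in that order, for 24 interferon genes 0.0839, 0.229 and 0.0736, and for 21 targets of YAP and TAZ 0.388, 0.512 and 0.963, with 0 of the latter called in any of the 3. Under high shear 1 NF-kB gene was called higher and 4 lower, as were 1 and 4 interferon genes, beside 1317 of all 20287 genes. Under low shear both lists had 1 higher and 3 lower, beside 1201 genes in all. Limma's fry test for changes in either direction gave adjusted p of 3.6e-06 for NF-kB and 4.0e-09 for interferon genes under high shear. It gave 0.171 for the YAP and TAZ targets. The interferon list was called for high shear with median scaling (adjusted p = 0.0465) and without the 2 high-background arrays (0.0206), with 0.178 and 0.106 with an estimated correlation, and without the latter also for low against high shear (0.0414, and 0.233 with an estimated correlation).

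For 24 genes of the unfolded protein response the adjusted p was 0.373, 0.167 and 0.147, for 5 venous genes 0.881, 0.517 and 0.147, for 9 smooth muscle, pericyte and fibroblast markers 0.472, 0.561 and 0.569, and for 5 leukocyte and erythroid markers 0.667, 0.555 and 0.532. These camera tests also ask for a shared direction. Of the smooth muscle, pericyte and fibroblast markers, 1 was called higher and 1 lower under high shear. Their adjusted p by fry for changes in either direction was 1.3e-05 there. Between reversing flow and low shear the leukocyte and erythroid list had a median of 0.82 and an adjusted p of 0.0501, 0.0325 with the experiment as a block and 0.0361 with median scaling (0.788 and 0.744 with an estimated correlation).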
